A study of Mus musculus with 24 samples.

How the data were processed

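The study sequenced RNA of 2 B cell subsets sorted from spleen, follicular (FO) and marginal zone (MZ), of TLR9 wild-type and TLR9 knockout male BALB/c mice, unstimulated or given CL097 at 5 ug/ml for 4 h, on a NextSeq 2000. There were 24 libraries in 8 groups of 3. According to the submitters' notes, the authors checked reads with FastQC 0.11.7, trimmed them with Trim Galore 0.6.5, aligned them to mm10 with STAR 2.6.1a, counted them with featureCounts of Subread 2.0.1 and compared groups with limma. The annotation, the normalisation and any batch term were not given in the sources used here.

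The deposited values are log2 values, one matrix per subset of 12 libraries and 23420 genes, and not counts. Raised to the power of 2 they add up to nearly the same total in each library, as CPM (counts scaled to the library total) do. Checked on the files, the sorted values of the 12 FO libraries were nearly the same, as after quantile normalisation (median deviation at most 0.009). Those of the MZ libraries were less so (at most 0.081), and MZ wild-type unstimulated replicate 1 had 6552 genes above log2 0 against 9498 or more in the others. The most common value, the floor, differed between the FO and MZ matrices (−4.69 and −4.60), so the subsets had been normalised apart. In 516 FO and 536 MZ genes the files held 1 value for each replicate number of the titles, and these differed between the numbers, while no gene did so for the numbers in the source names. Such values arise when each gene is shifted by the replicate number of the titles after the log. In genes read in 1 library only (844 FO, 915 MZ), the ratio of that library's deviation to the shift had a median of 8.99 in each subset and lay within 5% of 9 in 729 and 826 genes. This is what a balanced adjustment over 18 libraries, 6 per number, would give, against the 12 libraries deposited per subset. The 2 sets of numbers differ in 9 wild-type samples, and the numbers of the titles are used throughout. The adjustment had removed the shift by number common to the libraries it covered, so pairing of samples by number could not be tested on that shift. Differences between genotypes within a number remained. In FO cells, the knockout minus wild-type differences of numbers 1, 2 and 3 correlated across genes between unstimulated and CL097 at 0.407, 0.551 and 0.364. Those of unlike numbers correlated between the conditions at 0.104 to 0.502. Whether a number marks 1 mouse was not tested on them. Depth per library is unknown, so no counting interval or floor was computed.

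A fit on counts with all 24 libraries had been planned and could not be run on log2 values. Each subset was fitted with limma 3.58.1 in R 4.3.3 instead, with a mean for each of its 4 groups, moderated variances with a mean-variance trend and no block, leaving 8 residual degrees of freedom, which do not count those the authors' adjustment had used. Genes were tested if their value was at least 0 in at least 3 libraries of the subset (10577 FO, 10276 MZ). The threshold was an adjusted p (Benjamini-Hochberg within each comparison) below 0.05. The 8 comparisons within subsets were CL097 against unstimulated in each genotype and knockout against wild type in each condition. The interaction of genotype and CL097 was tested within each subset, and interactions with subset on the 10086 genes kept in both, in a fit of all 24 libraries. The second fit had the replicate number as a block (6 residual degrees of freedom), which had been planned. In MZ cells it was also, by a choice made after the values had been seen, without wild-type unstimulated replicate 1, the library of few detected genes (5 residual degrees of freedom, 10251 genes, n = 2 in that group). SDs given for the second fit are of values from which the shift by replicate number was removed. Where the text says "without the low library" it means this second fit. Leaving out 1 library leaves a group of 2 or more, and limma pools the spread over groups.

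Comparisons, lists, the rule for named genes and the alternatives were fixed before the data were examined, except where the text says otherwise. The text names, for each comparison, the 10 genes with the largest rise and the 10 with the largest fall (5 and 5 for CL097 in knockout cells) among those past the threshold. These had to have a mean of at least 5 CPM in the higher group and no overlap between the replicates of the 2 groups. For an interaction the mean was that of the highest of its groups, and overlap was not checked. Predicted genes and receptor variable segments were left out. It also names up to 4 members of each list, those past the threshold with the largest change or else those of highest mean, and, whatever their values, Tlr9, Tlr7, Unc93b1, Il6, Il10, Cd69, Cd86, Myc, Aicda, Prdm1, Irf4, Tbx21, Cr2, Fcer2a, Cd1d1, Ighm and Ighd. Genes within 20 Mb of Tlr9 past the threshold in all 4 comparisons of genotype were to be named too. For MZ cells and for the subset responses, the genes of the second fit are named as well.

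The 28 gene lists were tested with camera of limma, with a preset correlation of 0.01, where at least 3 members were tested, and adjusted over the lists of a comparison; members were also adjusted over the list alone. They are TLR sensing and signalling, NF-kB targets and feedback, immediate-early genes, type I interferon-stimulated genes, cytokines and chemokines, B cell activation receptors, plasma cell differentiation, unfolded protein response, class switching and germinal centre, age-associated B cell genes, ribosome biogenesis and MYC targets, glycolysis, sterol synthesis and cell cycle. Further lists are BCL2 family, inhibitory receptors and negative regulators, B cell receptor signalling, MHC class II presentation, lymphocyte trafficking, markers of follicular, marginal zone, B-1, T and NK, myeloid, dendritic and erythroid or platelet cells, heat shock, and mitochondrially encoded genes. Some genes are in several lists, such as Irak3 and Tnfaip3. Positions and transcript lengths came from the reference annotation, which matched 23260 and 23052 of the 23420 symbols.

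The fit was tested on simulated data, with log2 changes of 0.5, 1 and 2 given to 67, 67 and 66 genes of each subset: FO recovered 20.9%, 56.7% and 98.5% and MZ, without the low library, 14.9%, 65.7% and 93.9%, and 2 and 5 unchanged genes were called. The simulated noise was normal and independent between libraries, and no other gene differed between groups. The changed genes all had a mean above 5 CPM, so the shares may not hold for genes of lower level or for many changed genes. Alternatives were other filters, 1 CPM added before the log, no variance trend, only the groups compared and all 24 libraries in one fit. Further ones were blocks by title number, by source-name number and within genotype, a correction for transcript length and GC content (loess, span 0.3), a minimum log2 fold change of 1, and leaving out each library. For lists they were camera with an estimated correlation, fry and lists without shared genes. Wild-type MZ and FO cells were not compared, since the matrices had been normalised apart, and tests and scalings that need counts were not run. Immunoglobulin genes are not in the files, so the alternative without them is void. Tables were written with python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.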

Results

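RNA was sequenced from B cells sorted from the spleens of male BALB/c mice labelled as wild type or knockout for TLR9, the endosomal receptor for unmethylated CpG DNA. Follicular (FO) cells were sorted as CD19+ CD23hi CD21lo and marginal zone (MZ) cells as CD19+ CD23lo CD21hi, both without T cell receptor. Cells were given CL097, an agonist of TLR7, at 5 ug/ml for 4 h or left unstimulated, and the labels do not say whether unstimulated cells spent that time in culture. The 24 libraries made 8 groups of 3, so that each combination of subset, genotype and stimulation had n = 3. The submitters state 3 mice per genotype, so libraries of different groups share animals, but not which libraries came from the same mouse. The files hold log2 values for 23420 genes and no counts, so the depth of each library is unknown and no counting interval can be given. Of these genes, 7363 stood at one shared low value of −4.69 in all 12 FO libraries and 6996 at one of −4.60 in all 12 MZ libraries, here called the floor. Some values lie below it. A library with few detected genes stood apart: MZ wild type unstimulated replicate 1 had 6552 genes above log2 0, against 9498 to 9950 in the other 11 MZ libraries. All adjusted p values are from limma. The log2 fold changes below are given ± the standard error of the fit, and groups are given as mean ± SD of the deposited log2 value.

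The first comparison asked what CL097 changed in wild-type FO cells. CL097 raised the chemokine gene Ccl3 from 1.66 ± 0.45 to 9.14 ± 0.12 (log2 fold change 7.49 ± 0.24, adjusted p = 6.38e-10). Tnf, which encodes tumour necrosis factor, rose by 5.97 ± 0.51 (adjusted p = 9.22e-07), and Hnf1b, a homeobox transcription factor, by 7.64 ± 0.80 (adjusted p = 5.4e-06). Itgb7, the integrin beta-7 chain used in homing to mucosa, fell by 3.02 ± 0.14 (adjusted p = 1.26e-08), and Cdc25b, a phosphatase that acts on cyclin-dependent kinases, fell by 3.05 ± 0.17 (adjusted p = 4e-08). Of 10577 genes tested, 5191 passed the threshold, 2552 higher and 2639 lower, and 4721 did so with the replicate number as a block. The other genes with the largest rises were Rhbdl3, Slc7a3, Ocln, Mgll, Itln1, Mfsd2a and Utf1, with log2 fold changes from 5.96 for Utf1 to 9.08 for Rhbdl3. In unstimulated cells Rhbdl3 (−4.23 ± 0.86), Slc7a3 (−4.23 ± 0.37) and Ocln (−4.69 ± 0.23) lay near the floor, so that their fold changes rest on the constant added before the log and are no bounds. The other genes with the largest falls were B3gnt8, Hepacam2, Ppap2b, Ceacam1, Xkrx, Serp2, Tspyl4 and Gpr146, from −3.60 for B3gnt8 to −2.96 for Gpr146. In each gene named by size of change in a comparison of 2 groups, here and below, all libraries of one group lay above all of the other. Chance gives this in 10% of genes for 3 against 3 and more often for 2 against 3. For the second fit it was checked after the shift by replicate number was removed, and for interactions it was not asked.

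The gene lists showed which groups of genes moved together in FO wild-type cells. Of 22 NF-kB targets and feedback genes tested, 18 rose, 0 fell and 4 did not pass (19 higher adjusted over the list alone). Nfkbiz (5.06 ± 0.17) and Gadd45b (3.72 ± 0.16) were among them, and the list moved up against other genes (adjusted p = 1.55e-10, and adjusted p = 0.0186 with an estimated correlation). All 30 ribosome biogenesis and MYC target genes rose, 30 also adjusted over the list alone. Myc itself was at 3.75 ± 0.12, Polr1b at 2.91 ± 0.16 and Srm at 2.72 ± 0.23 (list adjusted p = 3.71e-18, and adjusted p = 0.0708 with an estimated correlation). Of 19 cytokine and chemokine genes, 13 rose and 3 fell, as they did adjusted over the list alone. Il12b at 6.54 ± 1.40 and Ccl22 at 6.44 ± 0.95 were among the rises (list adjusted p = 0.000364, and adjusted p = 0.049 with an estimated correlation). Of 19 B cell activation receptors, 15 rose and 2 fell, as they did adjusted over the list alone. Il2ra, the alpha chain of the IL-2 receptor, was at 4.79 ± 0.14 and Cd44 at 2.95 ± 0.14 (list adjusted p = 7.57e-06, and adjusted p = 0.0179 with an estimated correlation). The class switching and germinal centre list had 8 higher and 2 lower of 17 (8 and 3 adjusted over the list alone), with Batf at 4.02 ± 0.14 (adjusted p = 0.0468, and adjusted p = 0.181 with an estimated correlation). Sterol synthesis had 11 higher and 2 lower of 22 (12 and 3 adjusted over the list alone), with Idi1 at 2.03 ± 0.21 and Sqle at 1.64 ± 0.16 (adjusted p = 0.0118, and adjusted p = 0.443 with an estimated correlation). In the BCL2 family, 7 of 15 rose and 3 fell, as they did adjusted over the list alone, and the survival gene Bcl2l1 rose by 4.57 ± 0.18 (adjusted p = 0.0355, and adjusted p = 0.397 with an estimated correlation). Heat shock genes had 6 higher and 1 lower of 11, also adjusted over the list alone, with Hspd1 at 1.66 ± 0.17 (adjusted p = 0.0292, and adjusted p = 0.316 with an estimated correlation).

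Genes of antigen receptor signalling, antigen presentation and migration went the other way in these cells. Of 20 B cell receptor signalling genes, 13 fell and 1 rose, as they did adjusted over the list alone, among them Btk (−1.29 ± 0.12) and Cd79a (−1.16 ± 0.09) (adjusted p = 0.00127, and adjusted p = 0.316 with an estimated correlation). In MHC class II presentation, 10 of 15 fell and 0 rose, also adjusted over the list alone, with H2-Oa at −1.59 ± 0.20 and H2-DMa at −1.51 ± 0.16 (adjusted p = 0.000342, and adjusted p = 0.0708 with an estimated correlation). Of 18 lymphocyte trafficking genes, 12 fell and 3 rose, also adjusted over the list alone. S1pr1, the receptor that guides exit from lymphoid organs, was at −2.46 ± 0.17, while Ccr7 was at 1.60 ± 0.10 (adjusted p = 0.0147, and adjusted p = 0.316 with an estimated correlation). The other 15 lists with at least 3 genes tested did not pass the list test, with adjusted p from 0.208 to 0.969. Members of 13 of them went both ways, with 6 higher and 6 lower of 27 TLR sensing and signalling genes, 6 and 7 of 20 immediate-early genes, and 9 and 7 of 32 type I interferon-stimulated genes. There were 2 and 5 of 12 plasma cell differentiation genes, 4 and 5 of 20 unfolded protein response genes, and 7 and 6 of 14 age-associated B cell genes. Glycolysis had 6 higher and 5 lower of 18, the cell cycle 4 and 6 of 23, and inhibitory receptors and negative regulators 5 and 10 of 21. Markers of the subsets counted 3 and 4 of 9 for follicular cells, 3 and 5 of 14 for marginal zone cells, and 4 and 1 of 9 for B-1 cells. Among markers of other cell types, 2 of 7 T and NK cell genes (Il7r 3.71 ± 1.15, Nkg7 3.17 ± 0.89) and 1 of 8 myeloid genes (Hmox1 0.86 ± 0.33, not with the replicate block) rose. Of 5 dendritic cell genes, 2 rose (Flt3 3.51 ± 0.31, Zbtb46 2.73 ± 0.20) and 1 fell. No erythroid or platelet marker was high enough to be tested, and no mitochondrially encoded gene was in the files. For the immediate-early, interferon, plasma cell, unfolded protein response and cell cycle lists, the median, the mean and the list test did not all have the same sign.

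In FO cells of the knockout, the same question was asked of CL097. Ccl3 rose by 7.69 ± 0.24 (adjusted p = 3.63e-10), Ccl4 by 6.26 ± 0.21 (adjusted p = 7.68e-10) and Nfkbiz by 6.14 ± 0.17 (adjusted p = 1.25e-10). Hnf1b and Ocln were also among the largest rises, from −3.26 ± 1.96 to 7.32 ± 0.61 and from −4.13 ± 0.76, near the floor, to 2.81 ± 0.25. The largest falls were in B3gnt8 (−3.75 ± 0.28), Cbx8 (−3.27 ± 0.32), Ndc80 (−3.02 ± 0.40), Hadh (−3.00 ± 0.29) and Itgb7 (−2.96 ± 0.14). Of 10577 genes, 4759 passed, 2286 higher and 2473 lower, and 4258 with the replicate block. The 11 lists that passed in wild-type cells also passed here. Of 22 NF-kB genes, 19 rose (19 adjusted over the list alone, adjusted p = 7.81e-12, and adjusted p = 0.0128 with an estimated correlation). So did 29 of 30 ribosome biogenesis and MYC target genes (30 adjusted over the list alone, adjusted p = 1.2e-18, and adjusted p = 0.0717 with an estimated correlation). Cytokines and chemokines (adjusted p = 0.000243) and activation receptors (adjusted p = 2.44e-06) also held with an estimated correlation, at adjusted p = 0.0403 and 0.0128. The remaining 7 lists did not, with estimated-correlation adjusted p of 0.113 for class switching, 0.423 for sterol synthesis, 0.265 for the BCL2 family, 0.346 for B cell receptor signalling, 0.0829 for MHC class II, 0.366 for trafficking and 0.324 for heat shock. The unfolded protein response, cell cycle, follicular and myeloid lists had a median, mean and test of unlike sign. Of the myeloid markers, Hmox1 (1.41 ± 0.33) and Emr1 (0.85 ± 0.29) rose, the latter not with the replicate block.

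In wild-type MZ cells, CL097 changed 2042 of 10276 genes, 979 higher and 1063 lower. Without the library of few detected genes and with the replicate block, 5574 of 10251 passed, 2838 higher and 2736 lower, and 2033 of the 2042 were among them in the same direction. Leaving out that library alone gave 2818, and the block alone 1804. The fit with both was chosen after the values had been seen and leaves n = 2 in the wild-type unstimulated group, and the values that follow are from it. Il6, a cytokine gene, rose from −0.31 ± 0.15 to 7.40 ± 0.15 (log2 fold change 7.71 ± 0.21, adjusted p = 1.4e-08), and Bcl2l1 rose by 6.14 ± 0.17 (adjusted p = 1.4e-08). Nfkbiz rose by 6.63 ± 0.22 (adjusted p = 2.12e-08), Ccl3 by 6.16 ± 0.31 (adjusted p = 2.54e-07) and Il1a by 5.54 ± 0.56 (adjusted p = 1.84e-05). The other largest rises were in Hnf1b (9.28 ± 0.30), Rhbdl3 (7.50 ± 0.58), Il12b (7.23 ± 0.35), Bcl2a1a (5.97 ± 0.32) and Ocln. Il12b was at −4.69 ± 0.05 in unstimulated cells, so that its fold change is no bound. The largest falls were in Mgst1 (−4.96 ± 0.35), B3gnt8 (−4.78 ± 0.35), Rnase6 (−4.68 ± 0.24), the thromboxane receptor gene Tbxa2r (−4.65 ± 0.27), Sh2d3c (−4.45 ± 0.22), the beta-2 adrenergic receptor gene Adrb2 (−4.34 ± 0.23), Dpysl2, Sgsh, Plekho1 and Ccng2. With all 12 libraries, the largest changes also included rises in Utf1, Il1b, Fam89a, Il2ra and Batf and falls in Stox1, March1, Cpt1a, Rapgef4 and Rab3d. There the median log2 fold change of all genes was 0.48, against 0.02 without that library.

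Of 22 NF-kB genes in MZ wild-type cells, 21 rose, also adjusted over the list alone (adjusted p = 1.26e-10). In that subset 17 of 21 cytokines and chemokines rose and 2 fell (adjusted p = 3.8e-07), and 17 of 20 activation receptors rose and 3 fell (adjusted p = 1.11e-05), with the same counts adjusted over the list alone. Ribosome biogenesis and MYC targets had 26 of 30 higher in both countings, with Myc at 2.87 ± 0.09 and Rrs1 at 1.95 ± 0.17 (adjusted p = 1.26e-10). Of 14 marginal zone markers, 10 fell and 2 rose in both countings, among them the falls of Hes5 (−2.68 ± 0.32), a target of Notch signalling, Mzb1 (−2.35 ± 0.11) and S1pr3 (−1.97 ± 0.29) (adjusted p = 0.00435). B cell receptor signalling had 14 lower and 1 higher of 20 in both countings, with Cd79b at −2.29 ± 0.13 (adjusted p = 0.00013). MHC class II presentation had 10 lower and 0 higher of 15 (1 higher adjusted over the list alone), with the class II transactivator gene Ciita at −2.26 ± 0.25 (adjusted p = 0.00129). Trafficking genes had 11 lower and 4 higher of 18, with S1pr1 at −3.62 ± 0.16 and Ccr7 at 3.28 ± 0.11 (adjusted p = 0.0264). Heat shock genes had 6 higher and 0 lower of 11 (adjusted p = 0.0331), and both counts were the same adjusted over the list alone. With an estimated correlation, none of these 9 lists held. The adjusted p were then 0.141 for the NF-kB, activation receptor, ribosome and marginal zone lists, 0.197 for cytokines, 0.264 for B cell receptor signalling, 0.417 for MHC class II and 0.424 for trafficking and heat shock. With all 12 libraries, the estimated correlation kept NF-kB (adjusted p = 0.00486), ribosome biogenesis (adjusted p = 0.00702) and B cell receptor signalling (adjusted p = 0.0438). The other 17 lists had adjusted p from 0.116 to 0.89. The only erythroid marker tested, Beta-s, was at −1.46 ± 1.24 and did not pass, and the TLR, unfolded protein response, age-associated, sterol, cell cycle and inhibitory lists had a median, mean and test of unlike sign.

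In MZ cells of the knockout, CL097 changed 1862 genes, 884 higher and 978 lower, and all 1862 were among the 6264 (3198 higher, 3066 lower) that passed without the library of few detected genes and with the replicate block. In that fit Il6 rose by 7.44 ± 0.18 (adjusted p = 2.83e-09), Hnf1b by 10.13 ± 0.26 (adjusted p = 2.83e-09) and Ocln by 7.91 ± 0.40 (adjusted p = 1.2e-07). Rhbdl3 reached 5.36 ± 0.45 from −3.18 ± 0.99, and Il12b reached 3.40 ± 0.14 from −4.60 ± 0.16, near the floor. Dpysl2 (−4.46 ± 0.20), Ccng2 (−4.41 ± 0.17), B3gnt8 (−4.34 ± 0.31), Mgst1 (−4.25 ± 0.31) and Rapgef4 (−4.22 ± 0.18) fell most, and with all 12 libraries Abi3 (−4.21 ± 0.28) was also among them. The 9 lists that passed in wild-type MZ cells passed here too. In addition 17 of 37 type I interferon-stimulated genes rose and 3 fell, also adjusted over the list alone. Isg15 was at 2.92 ± 0.31 and Ifih1, a sensor of viral RNA, at 2.52 ± 0.21 (list adjusted p = 0.0247, and adjusted p = 0.838 with an estimated correlation). The other 9 lists had estimated-correlation adjusted p from 0.17 for the NF-kB list to 0.484 for heat shock, and the 16 lists that did not pass had adjusted p from 0.141 to 0.937. The TLR, unfolded protein response, inhibitory and T and NK cell lists had a median, mean and test of unlike sign. Of the myeloid markers, Lyz2 (−1.90 ± 0.57) and Cd14 (−1.69 ± 0.42) fell.

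**Figure D1:**
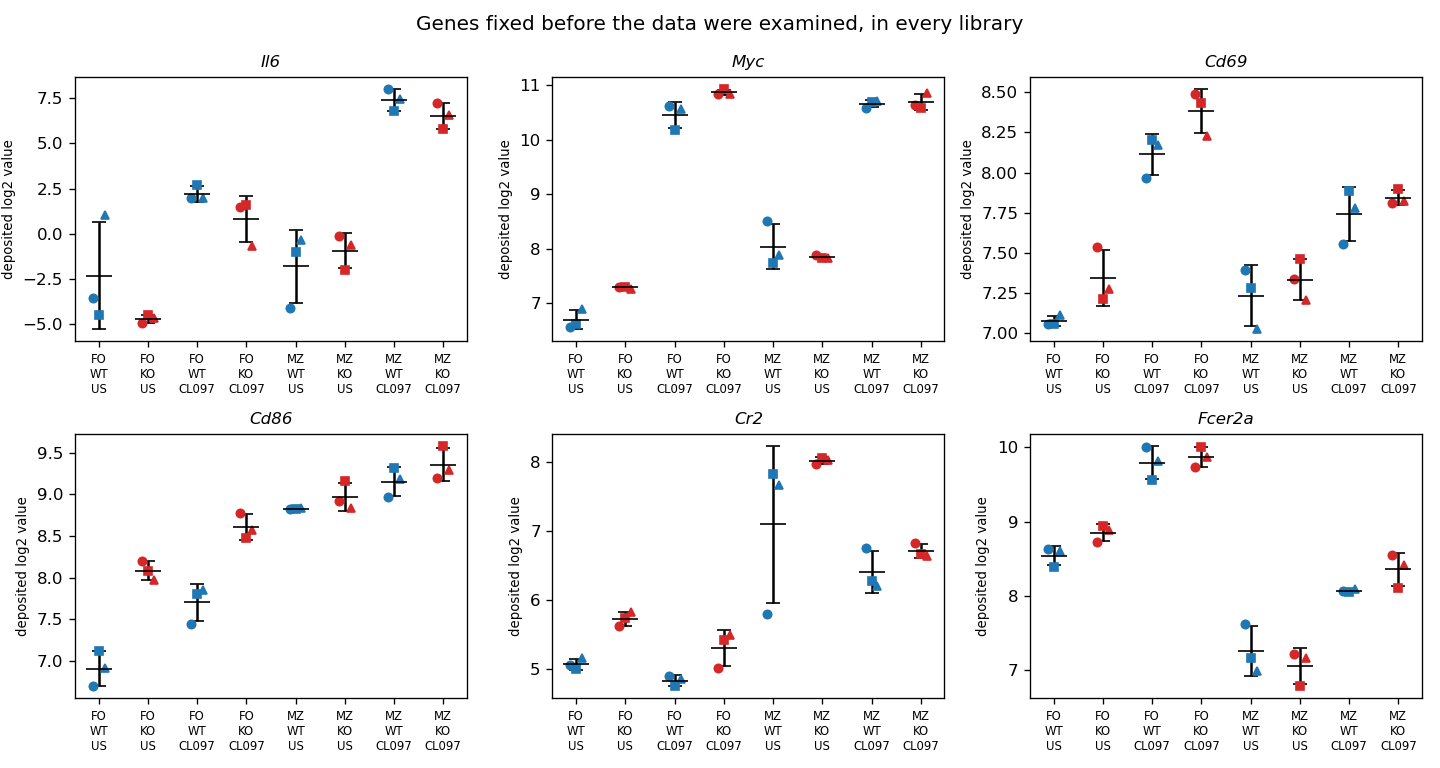
Deposited log2 values of Il6, Myc, Cd69, Cd86, Cr2 and Fcer2a in each of the 24 libraries by group, with wild type in blue and TLR9 knockout in red; circles, squares and triangles are replicates 1, 2 and 3, horizontal lines are means and bars are ± 1 SD. Myc lay at 10.45 ± 0.23 in FO wild-type cells with CL097 and at 6.70 ± 0.18 without, and Cd86 lay higher in FO knockout than FO wild-type cells in each condition.

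Several genes were followed in every comparison, whatever their rank. The activation marker Cd69 rose with CL097 in FO cells of both genotypes (1.04 ± 0.11 in each) and in MZ cells (0.62 ± 0.11 in wild type and 0.51 ± 0.10 in knockout). Cd86, a costimulatory ligand, rose in FO cells (0.80 ± 0.14 in wild type, 0.52 ± 0.14 in knockout) and in MZ cells (0.39 ± 0.10 and 0.39 ± 0.09). Il10 rose by 4.81 ± 0.86 and 5.01 ± 0.86 in FO wild-type and knockout cells and by 3.96 ± 0.21 and 4.47 ± 0.18 in MZ cells, and Il6 by 4.52 ± 1.17 and 5.51 ± 1.17 in FO cells. Il6 stood at the floor in unstimulated FO knockout cells (−4.69 ± 0.21) and reached 0.82 ± 1.27, so that fold change is no bound. In FO wild-type cells it went from −2.31 ± 2.97 to 2.21 ± 0.42. Unstimulated Il10 was also low in FO cells, at −3.47 ± 1.67 in wild type and −2.78 ± 1.44 in knockout. Irf4, a regulator of plasma cell formation, rose by 1.57 ± 0.14 and 1.52 ± 0.14 in FO cells and by 1.79 ± 0.14 and 1.80 ± 0.12 in MZ cells. Prdm1, another such regulator, did not pass in FO cells (0.49 ± 0.22 and 0.27 ± 0.22) and fell in MZ cells by 0.90 ± 0.33 and 0.77 ± 0.28. Cr2, which encodes CD21, was at −1.41 ± 0.14 and −1.31 ± 0.13 in MZ cells, and Fcer2a, which encodes CD23, rose in both subsets, by 1.25 ± 0.12 in FO and 0.94 ± 0.14 in MZ wild-type cells. Tbx21 rose in MZ cells (1.34 ± 0.23 and 1.57 ± 0.20) and did not pass in FO cells (−0.41 ± 0.23 and −0.32 ± 0.23). Tlr7 rose in FO cells by 1.93 ± 0.31 and 2.82 ± 0.31 and in MZ cells by 1.17 ± 0.20 and 1.26 ± 0.17. Unc93b1, which carries TLR7 and TLR9 to endosomes, was at −0.53 ± 0.12 in FO wild-type, −0.55 ± 0.14 in MZ wild-type and −0.57 ± 0.12 in MZ knockout cells, past the threshold in each, and at −0.28 ± 0.12 in FO knockout cells, where it did not pass (adjusted p = 0.083). In FO cells Aicda, the enzyme gene of class switching and hypermutation, rose in wild type (3.19 ± 0.87, adjusted p = 0.00826) and was at 0.18 ± 0.87 in knockout. Its unstimulated level was −1.99 ± 1.86 in wild type and 0.51 ± 0.29 in knockout, and its level with CL097 1.19 ± 0.91 and 0.69 ± 1.28. Aicda did not pass the test of the interaction of genotype and CL097 in FO cells. Ighm and Ighd were not in the files. All MZ values of this paragraph are without the library of few detected genes. With all libraries, Tlr7, Tbx21, Cd86, Cr2 and Prdm1 passed in MZ cells of neither genotype, and Unc93b1 in knockout MZ cells only. The wild-type MZ changes were then 3.57 ± 1.40 for Tlr7, 3.67 ± 1.36 for Tbx21 and 1.63 ± 1.48 for Prdm1.

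Tlr9, the gene named in the knockout, was measured in every library. In FO cells the knockout minus wild-type log2 difference was −0.69 ± 0.43 without stimulation (adjusted p = 0.294) and −1.13 ± 0.43 with CL097 (adjusted p = 0.104). In MZ cells it was 1.03 ± 1.60 without stimulation with all libraries (adjusted p = 0.626), −1.54 ± 0.49 without the library of few detected genes (adjusted p = 0.0529), and −0.94 ± 0.43 with CL097 (adjusted p = 0.163). Tlr9 passed the threshold in none of the 4 comparisons of genotype. By replicate number, the difference with CL097 was 0.21, −1.88 and −1.71 in FO cells and 0.57, −1.96 and −1.42 in MZ cells for replicates 1, 2 and 3. Unstimulated FO cells gave −0.49, −0.89 and −0.68, and unstimulated MZ cells −1.68 and −1.89 for replicates 2 and 3, with the low library as the wild type of replicate 1. Tlr9 rose with CL097 in FO wild-type (1.86 ± 0.43, adjusted p = 0.00316) and FO knockout cells (1.42 ± 0.43, adjusted p = 0.0172). Without the low library it rose in MZ knockout cells (1.23 ± 0.43, adjusted p = 0.0286) and did not pass in MZ wild-type cells (0.63 ± 0.495, adjusted p = 0.305). With all libraries it passed in neither (adjusted p = 0.785 and 0.171). The files give one value per gene, so which exons the reads covered is not known.

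**Figure D2:**
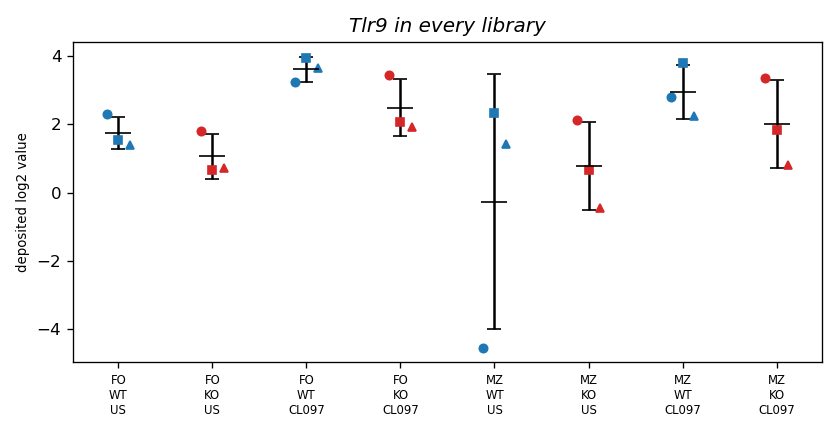
Deposited log2 value of Tlr9 in each of the 24 libraries by group, with wild type in blue and TLR9 knockout in red; circles, squares and triangles are replicates 1, 2 and 3, horizontal lines are means and bars are ± 1 SD. With CL097, knockout replicate 1 lies 0.21 above wild-type replicate 1 in FO cells and 0.57 above it in MZ cells, while replicates 2 and 3 of the knockout lie below their wild-type counterparts.

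The genotype comparison in unstimulated FO cells asked what differed in the knockout at rest. Knockout cells had more Rnpep, an aminopeptidase gene (3.83 ± 0.06 against −0.39 ± 1.16, log2 fold change 4.22 ± 0.88, adjusted p = 0.0188), and more Cd86 (1.18 ± 0.14, adjusted p = 0.00144). They had more Socs3, an inhibitor of cytokine signalling (1.69 ± 0.18, adjusted p = 0.00132), and more Mapk12, a p38 kinase gene (1.73 ± 0.21, adjusted p = 0.00174). They had less Sox4 (−2.32 ± 0.38, adjusted p = 0.00705), less Csrp1 (−2.10 ± 0.29, adjusted p = 0.00341) and less Cd93, a surface marker of immature and transitional B cells (−1.90 ± 0.22, adjusted p = 0.00144). Dock6, L1cam, Tsga14 and Tmem51 were also higher, by 1.60 to 1.85, and Cfp, Gh, Cplx2, Car13 and Hlx lower, from −1.86 for Cfp to −1.71 for Hlx. In all, 867 genes passed, 493 higher and 374 lower, and 245 of these passed with the replicate block, 141 higher and 104 lower. The block ended the calls of Tbc1d30 (1.77 ± 0.49), Arhgap5 (1.61 ± 0.45), Meis3 (1.59 ± 0.38), Cited2 (−1.82 ± 0.49) and Snx20 (−1.75 ± 0.48), at adjusted p from 0.0651 to 0.0842. The count was 2627 without knockout replicate 1, 105 without knockout replicate 2, 82 without knockout replicate 3, 490 without wild-type replicate 1 and 281 without wild-type replicate 2. Across genes, which are not independent replicates, the knockout minus wild-type differences of both subsets followed transcript length, with Spearman correlations of 0.203 to 0.354 in replicates 2 and 3 and 0.041 to 0.11 in replicate 1. The list tests of genotype were not corrected for this trend.

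Of the lists in unstimulated FO cells, 1 passed. Ribosome biogenesis and MYC targets had 10 of 30 genes higher and 0 lower in the knockout (14 and 0 adjusted over the list alone, and 4 higher with the replicate block). Tsr1 was at 0.94 ± 0.14 and Rrp12 at 0.88 ± 0.18 (list adjusted p = 4.22e-05, and adjusted p = 0.73 with an estimated correlation). Myc was at 0.59 ± 0.12 (adjusted p = 0.0153) and Irf4 at 0.68 ± 0.14 (adjusted p = 0.0157). The other 25 lists had adjusted p from 0.123 to 0.92, and 6 of 21 inhibitory receptors and negative regulators were higher and 3 lower, among them Irak3, a brake on TLR signalling (1.04 ± 0.15), and Tnfaip3 (1.01 ± 0.18). Il12a (−0.90 ± 0.11) and Ltb (−0.78 ± 0.14) were lower among the cytokines, and 0 of 32 interferon-stimulated genes passed by limma. Marginal zone markers went both ways, with Cd1d1 at −1.39 ± 0.31 (adjusted p = 0.06 with the block), Plac8 at −0.81 ± 0.18 and Cr2 at 0.66 ± 0.14. Of markers of other cells, Emr1 was lower (−1.42 ± 0.29) and Flt3 higher (1.58 ± 0.31). The plasma cell, follicular, marginal zone, B-1, myeloid and dendritic lists had a median, mean and test of unlike sign.

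With CL097, FO knockout cells again had more Rnpep (4.80 ± 0.88, adjusted p = 0.0118), Mapk12 (1.67 ± 0.21, adjusted p = 0.00263) and Cd86 (0.91 ± 0.14, adjusted p = 0.00561) than FO wild-type cells. They had more Pmaip1, which encodes the pro-apoptotic protein Noxa (1.66 ± 0.24, adjusted p = 0.00497). They also had more Lax1, an adaptor of lymphocyte receptor signalling (1.57 ± 0.15, adjusted p = 0.000975), and more Malt1, the paracaspase that links antigen receptors to NF-kB (1.45 ± 0.28, adjusted p = 0.017). Less abundant were Gpr56 (−1.91 ± 0.20, adjusted p = 0.00141), Tifa, an adaptor of TRAF proteins (−1.48 ± 0.13, adjusted p = 0.000513), and Mgst1 (−2.23 ± 0.41, adjusted p = 0.0112). H60b, Vopp1, Tmem51 and Ppfibp1 were also higher, by 1.49 to 1.59, and Basp1, Csrp1, Cplx2, Ankrd55, Hes5, Cd93 and Cdkn2c lower, from −1.96 for Basp1 to −1.44 for Cdkn2c. Of 10577 genes, 697 passed, 362 higher and 335 lower, and 230 with the replicate block, 132 higher and 98 lower; the block ended the call of Chic1 (1.53 ± 0.36, adjusted p = 0.066). The count was 1871 without knockout replicate 1, 109 without knockout replicate 2, 96 without knockout replicate 3, and 322, 120 and 123 without wild-type replicates 1, 2 and 3.

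The list of lymphocyte trafficking genes passed with 5 of 18 higher and 0 lower (6 higher adjusted over the list alone, adjusted p = 0.00112), among them S1pr1 (0.85 ± 0.17), Ccr6 (0.84 ± 0.15) and Cxcr5 (0.67 ± 0.09). Immediate-early genes passed with 5 of 20 higher and 0 lower, also adjusted over the list alone, among them Nr4a2 (1.42 ± 0.29) and Egr2 (1.05 ± 0.20) (adjusted p = 0.0204). Inhibitory receptors and negative regulators passed with 7 of 21 higher and 2 lower (10 and 2 adjusted over the list alone), among them Irak3 (0.99 ± 0.15) and Inpp5d, the phosphatase SHIP1 (0.70 ± 0.15) (adjusted p = 0.0204). Activation receptors passed with 5 of 19 higher and 0 lower (6 and 1 adjusted over the list alone), among them Icosl (0.59 ± 0.10) (adjusted p = 0.0364). With an estimated correlation all 4 lost the call, at adjusted p = 0.586 for the immediate-early list and 0.282 for the other 3. The other 22 lists had adjusted p from 0.0581 to 0.956. Il12a (−0.66 ± 0.11), Ltb (−0.66 ± 0.14) and Batf (−0.75 ± 0.14) were lower. The marginal zone, B-1 and myeloid lists had a median, mean and test of unlike sign.

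Unstimulated MZ cells of the 2 genotypes differed in 3 genes with all libraries. Apoe (1.08 ± 0.10, adjusted p = 0.00848) and Btg2, an antiproliferative gene (1.09 ± 0.13, adjusted p = 0.0236), were higher in the knockout and Gp49a (−1.64 ± 0.20, adjusted p = 0.0298) lower. With the replicate block limma called 0 genes, these 3 included. At an unadjusted p below 0.05, 1686 genes passed with all libraries, and the median log2 fold change of all genes was 0.35. Without the library of few detected genes and with the replicate block, 1961 passed, 844 higher and 1117 lower, and the median was −0.01. That fit had no unstimulated wild-type library of replicate 1, so this comparison rested mainly on replicates 2 and 3. Their knockout minus wild-type differences were more like each other than like those of replicate 1. In unstimulated FO cells, leaving out knockout replicate 1 raised the count to 2627. How far this made up the 1961 was not tested. Leaving out the library of few detected genes alone gave 4 genes, with a median of 0.10, so the 1961 rest on the added block as well. The deposited values had been shifted by replicate number with that library among them. Leaving it out does not undo this shift, while the block can take it up. Whether this accounts for the difference between 4 and 1961 was not tested. Leaving out other single libraries gave 105 genes without knockout replicate 1, 0 without knockout replicate 2, 1 without knockout replicate 3, 5 without wild-type replicate 2 and 0 without wild-type replicate 3. In the fit without the low library, Rnpep was again higher (3.45 ± 0.28, adjusted p = 0.00127) and Csrp1 lower (−2.86 ± 0.26, adjusted p = 0.00274). Aicda (3.69 ± 0.62, adjusted p = 0.0156) and Gcsam, a germinal centre gene (3.85 ± 0.73, adjusted p = 0.0166), were higher. Ngp, a neutrophil granule gene, was at 4.27 ± 2.02 in the knockout and −3.00 ± 0.84 in the wild type. Slc35a3, Wdhd1, Rgs18, Zbtb38, Isoc1, Ostm1, Wrnip1 and Rbl2 were also higher, by 1.62 to 1.91, and Zscan25, Npm3, Mpst, Tsc22d1, Cd151, Tubb2b, Rab5c, Npm3-ps1 and Chtf8 lower, from −3.04 for Zscan25 to −2.33 for Chtf8.

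In that fit, 9 of 22 sterol synthesis genes were lower and 0 higher, also adjusted over the list alone. Among them were Dhcr24 (−1.67 ± 0.21), Pmvk (−1.30 ± 0.26) and Mvd (−1.06 ± 0.20) (adjusted p = 0.01, and adjusted p = 0.761 with an estimated correlation). B cell receptor signalling had 4 of 20 higher and 0 lower (6 higher adjusted over the list alone), among them Malt1 (1.26 ± 0.26) and Syk (0.52 ± 0.13) (adjusted p = 0.0158, and adjusted p = 0.761 with an estimated correlation). The other 24 lists had adjusted p from 0.0526 to 0.919, and 0 of 26 passed with all libraries. Irak3 (1.30 ± 0.17), Unc93b1 (0.63 ± 0.14) and Socs3 (1.21 ± 0.32) were higher, Hk2 lower (−1.30 ± 0.16), and 0 of the T and NK, myeloid or dendritic markers passed. The immediate-early, class switching, glycolysis, MHC class II, follicular, B-1 and dendritic lists had a median, mean and test of unlike sign.

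With CL097, 0 genes differed between MZ knockout and MZ wild-type cells with all libraries by limma, and 739 at an unadjusted p below 0.05. Without the library of few detected genes and with the replicate block, 967 passed, 466 higher and 501 lower. Rnpep (2.74 ± 0.24, adjusted p = 0.00301) and Lax1 (1.32 ± 0.19, adjusted p = 0.0134) were higher. Lower were Csrp1 (−2.29 ± 0.23, adjusted p = 0.00568), Basp1 (−1.65 ± 0.29, adjusted p = 0.0203) and Ly96, which encodes the TLR4 co-receptor MD-2 (−1.59 ± 0.21, adjusted p = 0.0124). Il6 was lower by log2 −0.89 ± 0.18 (adjusted p = 0.0295) and Aicda higher by 2.11 ± 0.54 (adjusted p = 0.0422). Txndc16, Rrbp1, Smg7, Ankrd11, Pramef8, Rbl2, Zfp180 and Numa1 were also higher, by 1.16 or more, and Npm3-ps1, Rpia, Sema7a, Cited2, Hira, Xlr and Cotl1 lower, from −1.90 for Npm3-ps1 to −1.47 for Cotl1. Cd1d1 was at −0.72 ± 0.18 (adjusted p = 0.0386), and Cd86 did not pass in MZ cells (0.20 ± 0.09, adjusted p = 0.147).

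In this fit 9 lists passed. B cell receptor signalling had 7 of 20 higher and 0 lower (10 higher adjusted over the list alone), among them Malt1 (1.03 ± 0.22) and Pik3ap1 (0.59 ± 0.12) (adjusted p = 0.000696). Ribosome biogenesis had 7 of 30 higher and 0 lower (11 adjusted over the list alone), among them Ncl (0.85 ± 0.14) (adjusted p = 0.000696). Inhibitory receptors and negative regulators had 7 of 21 higher and 0 lower (12 and 2 adjusted over the list alone), among them Dusp6 (1.13 ± 0.28) and Cd22 (0.94 ± 0.24) (adjusted p = 0.00699). TLR genes had 3 of 27 higher, also adjusted over the list alone, with Irak3, Unc93b1 and Irf8 (adjusted p = 0.00971). Interferon-stimulated genes had 3 of 37 higher in both countings, with the RNA sensor genes Ddx58 (1.07 ± 0.24) and Ifih1 (0.88 ± 0.21) (adjusted p = 0.00776). Cell cycle genes had 4 of 24 higher (7 adjusted over the list alone), with Mcm7 (0.81 ± 0.13) and Mcm4 (0.65 ± 0.15) (adjusted p = 0.0172). Trafficking had 3 of 18 higher and 1 lower (10 and 1 adjusted over the list alone, adjusted p = 0.00971). Activation receptors had 3 of 20 higher (4 adjusted over the list alone), with Icosl at 1.05 ± 0.14 (adjusted p = 0.024), and heat shock genes 2 of 11 higher and 1 lower (3 and 1 adjusted over the list alone, adjusted p = 0.0494). None of the 9 held with an estimated correlation, at adjusted p from 0.464 to 0.716. The other 17 lists had adjusted p from 0.0774 to 0.933, and the immediate-early and B-1 lists had a median, mean and test of unlike sign.

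Whether the genotype altered the response to CL097 was tested as the interaction of genotype and stimulation. In FO cells 1 gene passed, Fam89a, which rose by 5.31 ± 0.21 in wild type and 3.10 ± 0.21 in knockout (difference −2.21 ± 0.29, adjusted p = 0.0493). With the replicate block limma called 0 genes, Fam89a had adjusted p = 0.361, and 267 genes had an unadjusted p below 0.05. Leaving out any 1 of 11 of the 12 FO libraries also gave 0 genes, and leaving out wild-type unstimulated replicate 1 gave 2. In MZ cells limma called 0 genes both with all libraries (60 at an unadjusted p below 0.05) and without the low library (327). Ribosome biogenesis and MYC targets passed the list test in FO cells, with a smaller response in the knockout (adjusted p = 0.00385, and adjusted p = 0.924 with an estimated correlation). In MZ cells without the low library, 4 lists passed. The responses of interferon-stimulated genes, ribosome biogenesis (adjusted p = 3.47e-07 each) and sterol synthesis (adjusted p = 0.00134) were larger and that of myeloid markers smaller (adjusted p = 0.0057) in the knockout. Their adjusted p were 0.784 to 0.872 with an estimated correlation. With all libraries the ribosome (adjusted p = 2.34e-07, and adjusted p = 0.0514 with an estimated correlation) and glycolysis lists (adjusted p = 0.0156, and adjusted p = 0.104 with an estimated correlation) passed, the latter with a median, mean and test of unlike sign.

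The response to CL097 was also compared between the subsets. In wild-type cells 242 genes responded differently, 25 more positively and 217 more negatively in MZ than in FO cells, and 693 (226 and 467) without the low library and with the replicate block, 231 of the 242 among them in the same direction. In that second fit the response of Alpl, the tissue-nonspecific alkaline phosphatase gene, was 4.53 ± 0.21 in FO and 1.64 ± 0.12 in MZ cells (difference −2.89 ± 0.27, adjusted p = 1.78e-05). Asns, the asparagine synthetase gene, rose by 3.46 ± 0.33 in FO and 0.91 ± 0.12 in MZ cells, and Vegfa by 4.81 ± 0.30 and 2.30 ± 0.35. Ccr7 rose by 1.60 ± 0.10 in FO and 3.28 ± 0.11 in MZ cells, and Socs3 by 1.59 ± 0.18 and 4.13 ± 0.32. Cd200 and Btla, 2 genes of inhibitory ligand and receptor pathways, were at −0.08 ± 0.15 and −0.03 ± 0.12 in FO cells and rose by 2.15 ± 0.16 and 2.001 ± 0.17 in MZ cells. Slfn2 fell by 1.09 ± 0.09 in FO cells and rose by 1.02 ± 0.12 in MZ cells. In this fit 16 of 30 ribosome biogenesis and MYC targets had a lower response in MZ cells (20 adjusted over the list alone, adjusted p = 2.1e-12, and adjusted p = 0.242 with an estimated correlation). So did 5 of 14 marginal zone markers (5 lower and 1 higher adjusted over the list alone, adjusted p = 0.000212, and adjusted p = 0.113 with an estimated correlation) and 4 of 22 sterol genes (9 adjusted over the list alone, adjusted p = 0.00051, and adjusted p = 0.651 with an estimated correlation). NF-kB targets had 3 of 22 with a higher response, Cflar, Nfkbiz and Tnfaip3 (6 adjusted over the list alone, adjusted p = 0.00054, and adjusted p = 0.417 with an estimated correlation). With all libraries the median log2 difference of all genes was 0.20, and only the ribosome list passed, with 9 genes lower (18 adjusted over the list alone, adjusted p = 4.75e-15, and adjusted p = 0.0251 with an estimated correlation).

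In knockout cells, 86 genes responded differently between the subsets, 7 more positively and 79 more negatively in MZ cells. Without the low library and with the replicate block, 541 did, 187 and 354, with all 86 among them. With all libraries 8 lists passed: NF-kB targets had a higher response in MZ cells (0 members past the threshold by limma and 1 adjusted over the list alone, adjusted p = 7.02e-07, and adjusted p = 0.00154 with an estimated correlation). Lower in MZ cells were marginal zone markers (2 of 14, 4 adjusted over the list alone, adjusted p = 5.4e-06) and ribosome biogenesis (3 of 30, 4 adjusted over the list alone, adjusted p = 3.52e-06). So were B cell receptor signalling, sterol synthesis, the BCL2 family, trafficking and B-1 markers. With an estimated correlation these 7 had adjusted p from 0.159 to 0.417. The difference between the genotypes was also compared between unstimulated MZ and FO cells. There limma called 0 genes with all libraries (791 at an unadjusted p below 0.05, with 3 genes without FO wild-type replicate 3) and 1 in the second fit, Fam89a (−2.61, adjusted p = 0.00693). Ribosome biogenesis (adjusted p = 8.55e-09, and adjusted p = 0.188 with an estimated correlation) and sterol synthesis (adjusted p = 0.0159, and adjusted p = 0.784 with an estimated correlation) passed the list test there with all libraries, lower in MZ cells. The mean of the sterol list was above 0 (0.34), however, and its median below (−0.29). Wild-type MZ and FO cells were not compared directly, since each subset had been normalised on its own. For the wild-type subset count, leaving out FO CL097 replicates 1, 2 and 3 gave 154, 148 and 122 genes, and FO unstimulated replicates 2 and 3 gave 155 and 160. Leaving out MZ CL097 replicates 1 and 3 gave 136 and 148, and MZ unstimulated replicate 2 gave 388. For the wild-type MZ response, leaving out CL097 replicate 1 gave 1345 genes.

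The position of the genes that differed between genotypes was compared with that of Tlr9, which lies on chromosome 9 from 106222598 to 106226876 (GRCm38). Within 20 Mb of it, 12 of 224 genes tested differed in unstimulated FO cells (5.36%, against 8.27% of 10311 genes elsewhere, Fisher's exact test, two-sided p = 0.139, adjusted p = 0.556). With CL097, 11 of 224 did (Fisher's exact test, two-sided p = 0.412, adjusted p = 0.824). In MZ cells with all libraries, 3 genes were called without stimulation, none of them near Tlr9, and 0 with CL097. There the test could show little or nothing. Without the low library, p and adjusted p of Fisher's exact test were 0.793 and 0.793 without stimulation and 0.239 and 0.793 with CL097. Across the whole genome, 24 genes differed in all 4 comparisons of genotype in the fits with the replicate block, MZ without the low library. Of them, 10 lay on chromosome 1 (Fisher's exact test, two-sided p = 3.19e-07, adjusted p = 6.38e-06 over 20 chromosomes). These were Stat4, Stk17b, Ankrd44, Lax1, Btg2, Rnpep, Smg7 and Fam20b, higher in the knockout, and Mreg and Csrp1, lower, between 51987106 and 156719095. Of the other 14, Irak3, Cd83, Plek and Bank1 were higher in the knockout and none lay on chromosome 9. This set was chosen after the values had been seen, and no gene within 20 Mb of Tlr9 passed in all 4.

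**Figure D3:**
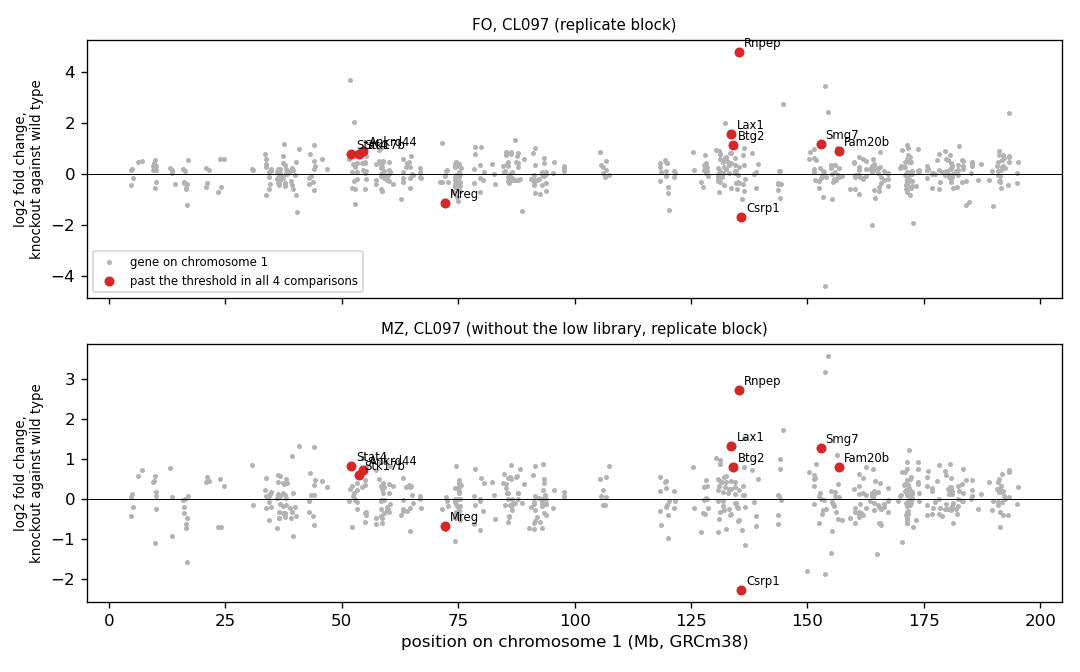
Log2 fold change of TLR9 knockout against wild type along chromosome 1 (position in Mb, GRCm38) with CL097, in FO cells with the replicate block (top) and in MZ cells without the library of few detected genes and with the replicate block (bottom). Each point is a gene and red points are the 10 genes past the threshold in all 4 comparisons of genotype, of which Rnpep lies at 4.80 in FO and 2.74 in MZ cells.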

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

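The interaction tests below were planned, while the fits without the low library, and all tests of the 3 patterns weighed after them, were chosen only after the result was seen. In FO cells the response to CL097 differed between the genotypes in 1 gene, Fam89a (−2.206 on the log2 scale, smaller in the knockout). With the replicate block 0 genes passed, so Fam89a lost its call. Between the subsets the response differed in 242 genes in wild-type cells and in 86 in knockout cells. These are differences between groups, each found by a test of the interaction. By the rule for named genes, the wild-type response was higher in MZ than FO cells by 1.901 for Egr1, 1.882 for Slfn2, 1.702 for Atp8b2, 1.568 for Siglecg, 1.504 for Fam43a, 1.44 for Ccr7, 1.35 for Stx11, 1.31 for Ube2h, 1.258 for Nup54 and 1.216 for Fh1. It was lower, by log2 differences of −4.064 for Mgst1, −3.641 for Vegfa, −3.407 for Zfp608, −3.255 for Plau, −3.154 for Rgs2, −3.12 for Asns, −3.104 for Alpl, −2.677 for Treml2, −2.596 for Gp49a and −2.532 for Rapgef4. Without the low library and with the replicate block all 20 kept their call, from an adjusted p of 2.39e-06 for Slfn2 to 0.0215 for Siglecg. With the block alone, Atp8b2, Siglecg, Fam43a, Ube2h, Nup54, Fh1, Vegfa, Zfp608, Plau and Gp49a lost it.

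MZ wild-type unstimulated replicate 1 had 6552 genes above log2 0, against 9498 to 9950 in the other MZ libraries. Whether the library held cells of another type could not be decided by markers of 4 other cell types. Of these, 5 of 58 lay over 1 above the other replicates, but only a marker above log2 0 could count. In this library 2 T and NK, 3 myeloid, 3 dendritic and 0 erythroid or platelet markers were above log2 0. Of them 2, 2, 1 and 0 lay over 1 above the other replicates. With low-level genes lost, the other markers could not show a rise, so this explanation stays open. A stimulated library under the wrong label is argued against by a slope of 0.092 on the CL097 response, where wild-type CL097 libraries had 0.922 to 0.927. Genes of low level were lost most: those between log2 0 and 2 in the other replicates had a median difference of −4.89 (38.9% within 0.5 of the floor), those between 2 and 4 one of −5.86 (8.9%) and those between 4 and 6 one of −0.2 (0.5%). This is in line with too few RNA molecules or reads in the library, which stays open with the depth unknown. No biological explanation was tested.

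Between knockout and wild type, the differences by replicate number were shared by replicates 2 and 3 more than by replicate 1: across genes, which are not independent replicates, the correlations between differences of numbers 2 and 3 were 0.284 to 0.712, those of number 1 with either −0.019 to 0.228, and those of number 1 with itself in another condition or subset 0.189 to 0.407. A trend on transcript length and GC content was present. Spearman correlations with length were 0.203 to 0.354 in numbers 2 and 3 and 0.041 to 0.11 in number 1. Those with GC content were −0.302 to −0.147 in numbers 2 and 3. In number 1 they were −0.063 in unstimulated FO, −0.072 in CL097 FO and 0.295 in CL097 MZ cells. The trend is argued against as the whole cause of the sharing. After its subtraction the lowest correlation between numbers 2 and 3 was 0.25, and those with number 1 reached 0.225 at most. It cannot be told apart whether the knockout libraries of replicate 1 came from wild-type animals. Their difference was set against that of replicates 2 and 3, over genes selected on replicates 2 and 3. Over 50 chromosome 1 genes the slope was 0.478 ± 0.235, 0.368 ± 0.137 and 0.467 ± 0.117 (jackknife SE) in unstimulated FO, CL097 FO and CL097 MZ cells. These slopes lay above 0 and below 1, and went down to 0.234 without Rnpep. Over 765 genes of the other chromosomes the slope was 0.12 ± 0.016, 0.063 ± 0.012 and 0.11 ± 0.015, above 0 but nearer to 0 than to 1. Replicate 1 differed in the direction of replicates 2 and 3 in 76%, 68% and 68% of the chromosome 1 genes. Of the other genes, 68.2%, 58.6% and 68.5% did so. Wild-type animals would give slopes near 0, and all of these lay above it. The jackknife treats genes as independent, which they are not, so its SE cannot decide this. Selection on replicates 2 and 3 by itself lowers the slope of replicate 1, so a slope below 1 does not decide. Nor can it be told apart whether these animals had kept Tlr9, with a knockout minus wild-type difference of at least 0.21 in the CL097 pairs of replicate 1, since the files hold no exon of Tlr9. Differences in the animals or their handling were not tested.

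Of 24 genes that differed in all 4 comparisons of genotype, 10 lay on chromosome 1, which does not hold Tlr9. A trend on length and GC content is argued against as the whole cause for 6 of the 10, which stayed past the threshold in all 4 after it was subtracted; after it, 33 genes did so, 8 of them on chromosome 1 (Fisher's exact test, two-sided p = 0.000419). The other 4 lost calls as the fold became smaller at a like SE: Stat4 in all 4 comparisons (0.86 ± 0.15 to 0.65 ± 0.17 in unstimulated FO cells) and 3 genes in 1 each, Ankrd44 (MZ unstimulated, 0.75 ± 0.21 to 0.59 ± 0.19), Smg7 (FO with CL097, 1.17 ± 0.24 to 1.02 ± 0.25) and Fam20b (MZ unstimulated, 0.73 ± 0.23 to 0.54 ± 0.20). A segment of another strain inherited with the knockout line may lie on chromosome 1, since the genes cluster there beyond what 20 chromosomes give (adjusted p = 6.38e-06). It remains a hypothesis, and an effect of TLR9 on these genes stays open as untested.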

How the results depend on the processing

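The alternatives with 1 CPM added, all 24 libraries in one fit, no variance trend, a correction for length and GC content, the block with only genes of known length, and without the low library were chosen after seeing the data; the others were planned. No list or gene named for a call in the fits with all libraries and no block had the opposite direction under any alternative that was run. Calls made only in the second fit were not covered by this check. Of genes named whatever their values and not called with all libraries, some changed sign without the low library. In unstimulated MZ genotype these were Tlr9 (1.033 to −1.536), Il6 (0.878 to −0.614), Il10 (1.832 to −0.188), Tbx21 (2.023 to −0.303), Cd1d1 (2.24 to −0.204) and Myc (−0.19 to 0.058). In the MZ wild-type response they were Prdm1 (1.632 to −0.901) and Cd1d1 (2.204 to −0.24).

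The balance of higher and lower calls turned under some alternative in each of the 7 comparisons within subsets that had calls. Unstimulated FO genotype went from 493 higher and 374 lower to 141 and 104 with the block and only genes of known length, 130 and 160 with length and GC content corrected besides, 10 and 14 with only the groups compared, and 11 and 13 with all 24 libraries. It went to 46 and 59 or 36 and 46 without knockout replicate 2 or 3. FO genotype with CL097 went from 362 and 335 to 763 and 840 with only the groups compared, 402 and 404 with 1 CPM added, and 886 and 985 without knockout replicate 1. The MZ wild-type response went from 979 and 1063 to 1444 and 1136 with 1 CPM added and 2798 and 1698 with all 24 libraries, and to more rises than falls without each unstimulated replicate. The counts of the 4 CL097 comparisons were 1031 or more under each, with 1031 to 5806 for the MZ wild-type response. Those of genotype ran from 24 to 2627 in unstimulated FO cells and from 37 to 1871 in FO cells with CL097. The MZ interaction of genotype and CL097 gave 0 genes under each. Depth is unknown, so what it limits cannot be said; in simulations with the spread of these libraries, a log2 change of 0.5 was found in 20.9% of FO and 14.9% of MZ genes. Except where a setting tests fewer genes or libraries or asks for a larger change, the cause was not tested.

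Without a filter on low values, FO genotype gave 573 genes unstimulated and 451 with CL097, the FO interaction of genotype and CL097 gave 3, and MZ genotype 5 and 2. With at least 5 CPM in 3 libraries, the FO interaction gave 0 and MZ unstimulated genotype 8. With 1 CPM added, the FO interaction gave 0. With no variance trend, FO genotype gave 480 and 328, the FO interaction 2 and MZ unstimulated genotype 0. With a log2 fold change of at least 1, the FO response gave 2418 in wild type and 2111 in knockout, FO genotype 207 and 143, and the subset difference in wild type 159. With only the groups compared, FO genotype gave 24 and 1603, the MZ wild-type response 1031, MZ unstimulated genotype 0 and the wild-type subset difference 55. With all 24 libraries in one fit, the FO response gave 2228 and 1963, FO genotype 24 and 37, the FO interaction 0, the MZ wild-type response 4496 and MZ genotype 572 and 8.

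With the replicate block, FO genotype gave 245 and 230, the FO interaction 0, MZ unstimulated genotype 0 and the wild-type subset difference 145. With blocks from the source names, FO genotype with CL097 gave 1116, the FO interaction 0 and MZ unstimulated genotype 7. With blocks within genotype, the FO interaction gave 0. Without the low library and with the block, the MZ response gave 5574 and 6264, MZ genotype 1961 and 967, the subset difference 693 in wild type and 541 in knockout, and genotype by subset 1. The settings that follow in this paragraph also left out the low library for MZ cells and for the comparisons between subsets. With the block and only genes of known length, FO genotype gave 245 and 230, the FO interaction 0, the MZ response 5538 and 6227, MZ genotype 1954 and 968, the subset difference 692 and 542, and genotype by subset 1. With length and GC content corrected besides, these were 290 and 285, 0, 5806 and 6527, 1838 and 909, 801 and 687, and 6. The subset differences were then 355 higher and 446 lower in wild type and 270 and 417 in knockout.

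The correlation of responses across genes, which are not independent replicates, was 0.613 between MZ wild type and knockout with all genes and libraries, 0.951 in the second fit and 0.94 over genes past the threshold in either. Between FO and MZ wild type it was 0.508, 0.82 and 0.617. For genotype, it was 0.552 between FO unstimulated and CL097 (0.786 with a mean of at least 5 CPM, 0.731 past the threshold in either) and 0.268 between MZ unstimulated and CL097 (0.753 in the second fit). It was 0.221 between unstimulated FO and MZ (0.528 in the second fit), and 0.615 between FO and MZ with CL097 (0.775 with at least 5 CPM, 0.791 past the threshold in either). The tests of position near Tlr9 kept their side of the threshold with 10 Mb and with the whole chromosome. In MZ cells with all libraries few or no genes were called, so this says little there.

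Leaving out each library gave 4462 to 4964 genes for the FO wild-type response, 3970 to 4420 for the FO knockout response, 1345 (without CL097 replicate 1) to 2818 (without unstimulated replicate 1, and no block) for MZ wild type and 1372 to 1600 for MZ knockout. For genotype it gave 82 to 2627 in unstimulated FO cells, without knockout replicates 3 and 1, and 96 to 1871 in FO cells with CL097, again without knockout replicates 3 and 1. In MZ cells it gave 0 to 105 unstimulated, the latter without knockout replicate 1, and 0 to 0 with CL097. The interaction of genotype and CL097 gave 0 to 2 in FO and 0 to 0 in MZ cells. The subset difference gave 122 (without FO CL097 replicate 3) to 388 (without MZ unstimulated replicate 2) in wild type and 60 to 88 in knockout, and genotype by subset 0 to 3.

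Of 124 calls of named genes, 104 held with the replicate block and 20 did not, and 122 held with 1 CPM added. With length and GC content corrected 117 held, in fits with the block and without the low library. Also 115 held without a filter, 116 without a variance trend, 119 with blocks from the source names and 119 of 120 with at least 5 CPM. Of 123 calls, 89 held with only the groups compared, and of 104 calls, 63 with all 24 libraries in one fit. Leaving out 1 library kept 730 calls and ended 140, and without the low library all 53 of 53 held. Of 65 list calls, 14 held with an estimated correlation, 46 with fry, 57 without genes of other lists and 65 with the replicate block. Of the 37 in MZ cells and in the interactions with subset, 31 held without the low library and 0 with an estimated correlation besides. DESeq2, voom, RLE factors, upper-quartile factors and CPM with TMM library sizes were not run, since they need counts, and the alternative without immunoglobulin genes is void, since the files hold none.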

Other observations

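The responses of both genotypes were alike in the genes they moved. In FO cells 1989 genes rose and 2115 fell in both wild type and knockout, where 551.6 and 617 would be shared if calls were independent. The slope of the knockout on the wild-type response was 0.80 over all genes (r = 0.872 across genes, which are not independent replicates). Over genes with a mean of at least 5 CPM it was 0.90 (r = 0.953), so the slope depends on the genes of low level. In MZ cells without the low library 2593 rose and 2515 fell in both, with a slope of 0.95. Between the subsets, 1829 genes rose and 1853 fell in both FO and MZ wild-type cells in the second fit, where 631.9 and 630.1 would be shared by independent calls. The genotype difference was shared between conditions as well. In FO cells 146 genes were higher and 166 lower in the knockout both without and with CL097, 55 and 42 with the replicate block, and in MZ cells without the low library 287 and 367. The independent numbers were 16.9 and 11.8, 1.8 and 1, and 38.4 and 54.6. The genotype comparisons without and with CL097 share no library, but with 3 mice stated per genotype they share animals.

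Among the 24 genes that differed in all 4 comparisons of genotype were Irak3, Cd83, a maturation marker of B cells, and Bank1, a scaffold of B cell receptor signalling, all higher in the knockout. Apoe, which encodes an apolipoprotein, and Scd1, a fatty acid desaturase gene, were also higher in all 4, and Tfe3, a transcription factor gene, was lower in all 4.

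The tests that follow, on other splits of the libraries, include fits with the planned replicate block and, for MZ cells, fits without the low library, which were chosen after the result was seen. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. In each of 6 comparisons the real split alone (1 of 10) gave as many genes as it did: FO wild-type response 5191 (highest other 2), FO knockout response 4759 (0), MZ wild-type response 2042 (0), MZ knockout response 1862 (0), FO unstimulated genotype 867 (0) and FO CL097 genotype 697 (0). The same was found for 6264 (0) and 967 (0) genes of the MZ knockout response and MZ CL097 genotype without the low library, and for 245 (0) and 230 (0) of FO genotype with the block. For MZ unstimulated genotype with all libraries, 2 of 10 splits gave at least 3 genes (highest other 11), and for MZ CL097 genotype the real count and that of every split was 0, which tests nothing.

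For interactions, 100 splits were drawn. Before counting, the difference common to both pairs was subtracted, a step chosen after counts without it had been seen, and it changed what can be said of 2 results. As many genes as in the real split were found in 1 of 100 splits for the subset difference in wild type (242, highest other 2) and in knockout (86, highest other 44). In 3 of 100 splits this was so for the FO interaction of genotype and CL097 (1, highest other 1501). Without the subtraction, 11 of 100 gave as many for each subset difference (highest other 3657 and 2123). For these 2 results chance can be excluded only with a step chosen after the counts were seen, and so is left open. The FO result is 1 gene, lost with the replicate block, and chance is left open for it too. For the MZ interaction (highest other 0) and for genotype by subset (highest other 4818) the real count was 0, so counting splits tests nothing. Splits with 1501 and 4818 genes, against real counts of 1 and 0, point to a structure of the samples or to the subtraction itself. Without the subtraction they were 3588 and 1222, so it lowered one and raised the other. What produced these counts was not tested.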
